A study of Caenorhabditis elegans with 2 samples.

How the data were processed

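Chromatin was immunoprecipitated through GFP from whole young adult worms of strain OP769 in 2 biological replicates, which the labels place in 1 group. Per the labels, chromatin was sheared by sonication and fragments of 200 to 800 bp were taken. The labels number the replicates as separate biological replicates; they do not say how the worm cultures were kept apart.

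The deposited files used here are 4 peak lists on assembly ce11 in narrowPeak format. Per the deposited file descriptions, each replicate's list was derived from that replicate's alignment and a control alignment, the pooled list from both replicates' alignments and the same control, and the optimal list from both replicates' lists and the pooled list, with a threshold on the irreproducible discovery rate (IDR), which measures how well ranks hold up between replicates. So the optimal peaks are pooled calls, and the replicates can be compared only through their own lists. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here. The deposited signal value of each peak is a score on the caller's own scale. The deposited summit is an offset in bp from the start of each peak. The level of the signal value differed between lists, with medians of 107 in the optimal list, 37.5 in the pooled list, 22.7 in replicate 1 and 20.6 in replicate 2, so its level was not compared between lists. It was used to describe, rank and filter peaks, to compare groups of peaks and regions within a list, and to correlate the replicates across peaks. All 407 optimal peaks were the 407 peaks of highest signal in the pooled list. The lists of 30000 peaks appear to end at a fixed number, so their full length was not compared.

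The control alignment enters every list. Regions that gather reads in any immunoprecipitation are not removed by comparison with such a control unless the control shows them too, and no list from an untagged strain was used here. Peaks had nearly one fixed width in each list (376 bp for 394 of the 407 optimal peaks), so a width says little about the extent of binding, and a summit is mostly the middle of its peak. Reads from near-identical gene copies, such as tRNA genes, may have been dropped or placed at random by the aligner, which makes single tRNA genes uncertain. Depth is unknown, since no read totals were used, so no peak can be weighed by its read count.

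Coordinates are ce11, the same assembly as WBcel235, and are 1-based. The lengths of all 6 nuclear chromosomes matched between the sequence and the annotation used. Genes and transcription starts came from Ensembl release 115, with 19973 nuclear protein-coding genes and 29304 distinct protein-coding starts, and tRNA identities came from the RefSeq annotation by matching coordinates. Genes were counted by identifier, since some symbols are shared by several genes. Each summit was placed in the first class that held it, in the order protein-coding TSS within 500 bp, 5′ UTR, coding exon, 3′ UTR, intron, other transcript and intergenic. A gene had a peak when an optimal summit lay within 500 bp of one of its starts, so neighbouring genes can share a peak, and tests that count genes treat them as independent except where summits or labels were shifted.

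Distance to starts and noncoding classes were tested by moving all summits of a chromosome together around it, 10000 times, which keeps their clustering (two-sided). Overlap of replicates was tested by 1000 such shifts of replicate 2 (one-sided), with a minimum overlap of 1 bp. Shares of the X chromosome and of the central 50% of the autosomes were tested with an exact binomial test. Protein-coding lists were tested with Fisher's exact test against all other protein-coding genes. The 29 lists and 7 noncoding classes formed 1 family of 36 tests with Benjamini-Hochberg adjustment at 0.05. The 12 fixed motifs were compared between windows of 201 bp at summits and equal windows centred 500 bp to a randomly chosen side by an exact McNemar test with the same adjustment, and all 2080 hexamers were counted alike as a description. Signal values and correlations had 100000 permutations. Intervals are exact (Clopper-Pearson) at 95%. Peaks and genes, not replicates, are the units of all these tests, so the p-values measure departure from chance placement in these lists and not variation between worm populations.

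The gene lists, the motifs, the main comparisons and their tests and alternatives were fixed before the data were examined. Chosen after seeing the data were 3 alternatives, the comparisons that the closing part names as such, and the counts by kind of small RNA gene. These alternatives were peaks away from small RNA genes, peaks away from tRNA genes, and overlapping optimal peaks merged. Also not fixed beforehand were the summit positions along tRNA and snoRNA genes and the shares of tRNA peaks and genes on X. The rank of the GC box core among hexamers made only of G and C was not either. The other alternatives changed the TSS window, the placement model, the strength of the peaks used, the overlap that counts as shared, the number of top peaks, the expected share, the motif window or background, and left out each replicate in turn by using the 407 strongest peaks of the other. The text names, by a rule fixed at the same time, the 25 strongest optimal peaks with a protein-coding TSS within 500 bp, the 5 strongest without one, up to 4 members of each list past the threshold, and sptf-2, unc-119 and the Sp and Krüppel-like list. Other genes named, such as cct-8, col-46, col-47, prp-40, rsp-2, the single members of lists that missed the threshold, and those in the closing part, were chosen after their values were seen.

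The steps were tested on simulated data. In 20 simulations of 407 random summits, a list of ribosomal protein genes with 20 planted starts, 40 planted tRNA starts and a motif planted in 30% of windows were each called 20 times. Without planting, 0 lists and 1 motif were called over the 20 simulations, and 1 simulation gave a p below 0.05 for distance to starts. Random summits do not differ from their flanks in base composition, while the real ones do (47.0% GC against 37.0%). The simulations therefore do not show how often composition alone leads to a motif call. The planted motif was also more frequent than the core GC box at real summits (12.3%). Of 200 planted shared peaks, 200 to 203 were found. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Signal tracks and alignments were not used here.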

Results

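The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for SPTF-2, a C. elegans zinc finger protein of the Sp family, whose mammalian relatives bind GC-rich promoter elements called GC boxes. Whole young adult worms of strain OP769, collected at 64.5 h, carried a transgene that makes SPTF-2 fused to eGFP and a FLAG tag, and chromatin was pulled down through the GFP. The series holds 1 group with 2 biological replicates and no second condition, so the questions it can answer are where the tagged protein was found in the genome and how alike the replicates were. The submitters' optimal set, thresholded on reproducibility between the replicates, held 407 peaks. The list of each replicate and the pooled list held 30000 peaks each. No read totals were analysed here, so the sequencing depth behind the peaks is unknown. All intervals below cover counting error over peaks or genes only.

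The gene of the tagged protein itself carried one of the strongest peaks. A peak at II:8625118-8625493 (ce11), with its summit at 8625306, lay 153 bp from the annotated transcription start site (TSS) of sptf-2 (WBGene00011926, plus strand, 8625459 to 8627622). Its signal value was 399 on the peak caller's own scale, rank 4 of the 407, and it stood at rank 3 in replicate 1 and rank 5 in replicate 2. A second, overlapping optimal peak had its summit at 8625506 and a signal of 110. Another optimal peak lay in an intron of sptf-2, with its summit at 8627014 and a signal of 92.1. Per the labels the tagged gene is part of a transgene, and reads from the transgene and from a native copy cannot be separated in the peak lists. The other 5 annotated genes of the Sp and Krüppel-like list, sptf-1, sptf-3, klf-1, klf-2 and klf-3, had no optimal summit within 500 bp of a TSS. An optimal peak lay in an intron of klf-1, 1279 bp from the nearest protein-coding TSS (III:2875909-2876284, signal 109.8, among the 407 strongest of replicate 2 alone). The list, 1 of 6 genes with a peak, did not pass its test (17.8-fold over expectation, two-sided Fisher's exact test, adjusted p = 0.180 over 36 tests). At unc-119, the rescue marker of the transgene (III:10902641-10908935), no optimal or pooled summit lay within 500 bp of a TSS. Replicate 1 alone listed a peak there, at rank 29419 of 30000.

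**Figure D1:**
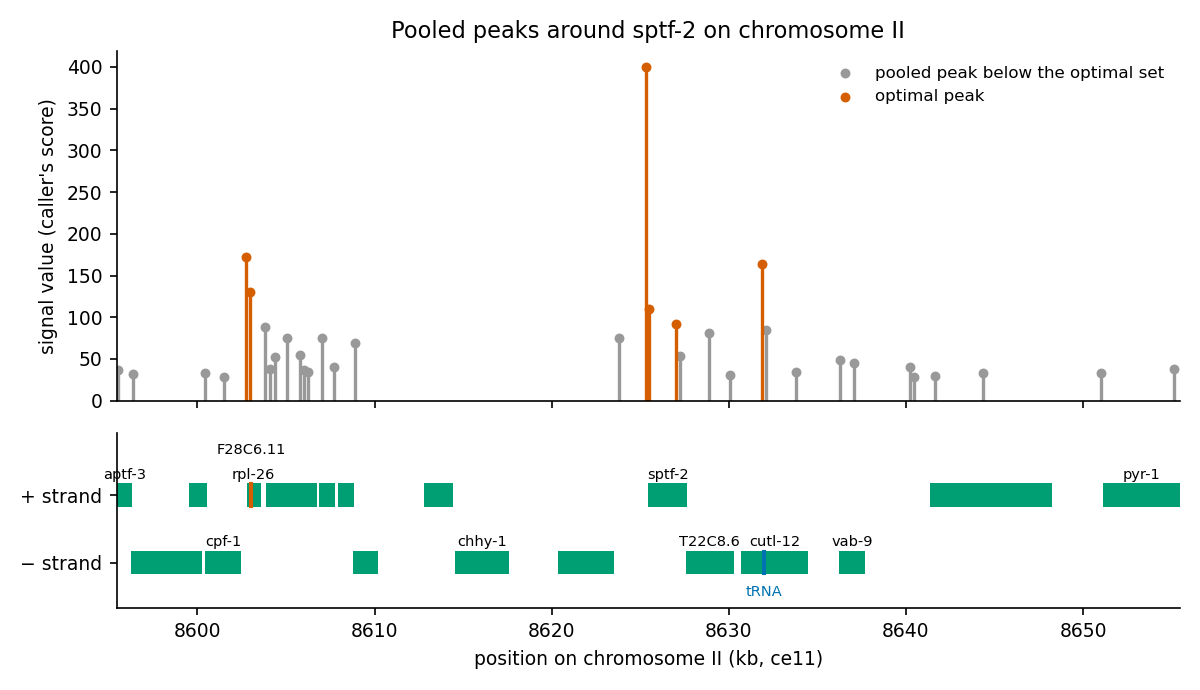
Pooled peaks within 30 kb of the sptf-2 start on chromosome II, with position in kb on the x axis and the signal value (the caller's score) on the y axis, above the annotated genes of each strand; orange marks the optimal peaks and grey the pooled peaks of lower rank. The tallest peak, at 399, stands just before the start of sptf-2, and the optimal peaks at rpl-26 (172) and at a tRNA gene inside cutl-12 (163) are also in view.

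A large part of the optimal set lay at genes for small noncoding RNAs. Of the 407 summits, 103 (25.3%, exact 95% interval 21.2 to 29.8) had a tRNA gene start within 500 bp, 62 (15.2%, 11.9 to 19.1) a snoRNA gene start and 14 (3.44%, 1.89 to 5.70) an snRNA gene start, each summit being counted once in that order. Small nucleolar RNAs (snoRNAs) guide the chemical modification of other RNAs, and small nuclear RNAs (snRNAs) take part in splicing. A further 117 summits (28.7%) had only a protein-coding TSS within 500 bp, and 111 (27.3%) had neither. Counted by gene, 122 of 612 annotated tRNA genes (19.9%, 16.8 to 23.3) had an optimal summit within 500 bp of their start, 43.8-fold more than when all summits were shifted together along each chromosome. For snoRNA genes the count was 63 of 346 (18.2%, 46.8-fold) and for snRNA genes 15 of 129 (11.6%, 32.7-fold). In windows of 1000 bp the folds were 25.2, 26.2 and 17.7 for tRNA, snoRNA and snRNA genes. Each of these classes had, in 500 bp windows, p = 0.0002, the smallest that 10000 circular shifts can give in a two-sided permutation test, and an adjusted p of 0.00117. Genes annotated only as ncRNA also passed the same permutation test, with 176 of 7764 at a peak (5.28-fold, adjusted p = 0.00117). Away from tRNA, snoRNA and snRNA genes the count was 60 (3.38-fold), and in windows of 1000 bp the fold was 3.29. Genes for piRNAs, germline small RNAs that silence transposons, lay at peaks less often than shifted summits gave, with 13 of 15363 against 56.3 expected (0.231-fold, permutation test, adjusted p = 0.00180). In the 204 strongest optimal peaks the piRNA fold was 0.295 and missed the threshold (permutation test, adjusted p = 0.0977), and away from small RNA genes it was 0.127, with 5 genes (adjusted p = 0.0115). For miRNA genes the count was 3 of 261 (2.69-fold, permutation test, adjusted p = 0.552). With the strongest 407 peaks of replicate 1 alone, that is without replicate 2, the miRNA fold was 8.05 (permutation test, adjusted p = 0.0122). Away from small RNA genes it was 4.97 and not past the threshold. None of the 20 rRNA genes had a peak, and whether reads can be placed at single copies of them was not checked.

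The snoRNA genes held the highest signal values. They accounted for 7 of the 10 strongest optimal peaks and 19 of the 50 strongest, and the median signal was 130 at snoRNA genes, 127 at snRNA genes, 112 at tRNA genes, 100.2 at protein-coding starts without a small RNA gene and 101 elsewhere. The strongest peak of all, with a signal of 645, lay at V:8500410-8500696 in an intron of pxn-1, which encodes a peroxidasin, with its summit just before the snoRNA gene ZK994.7 (8500579 to 8500645). The next, with a signal of 506, lay at V:12303484-12303762 in an intron of frm-7, with its summit inside the snoRNA gene C51F7.4 and close to a neighbour, C51F7.3. Peaks followed at the snoRNA gene T03F7.8 in an intron of cutl-18 (V:11314101-11314314, signal 408) and at the intergenic snoRNA gene W03C9.9 (II:11960682-11960917, signal 381). At rank 6, with a signal of 362, a peak at I:13463852-13464081 in an intron of ints-8, a subunit of the Integrator complex, covered the start of rpr-1, the gene for the RNA part of RNase P, which trims the 5′ ends of tRNAs. These 5 peaks had no protein-coding TSS within 500 bp.

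Among tRNA genes, the strongest peak (rank 11, signal 255) lay at X:9743509-9743884 in an intron of him-4, between a pair of tRNA genes, for which alanine was the isotype matched. The next 3 lay at X:6292159-6292534 (alanine, signal 192), X:5713479-5713854 (lysine, 176) and X:12563660-12564035 (threonine, 173). The strongest snRNA peaks lay at sls-2.4 (signal 199.6), R07E5.16 (181), sup-6 (174) and sls-2.1 (166). The sls-2 genes make the SL2 RNAs that are spliced onto downstream messages of operons. The summits sat close to the genes. Measured along the direction of transcription, the median summit lay 26.5 bp after the start of the tRNA gene, with 94.3% of 122 genes within 200 bp, and -23 bp from the start of the snoRNA gene, that is before it, with 57 of 63 within 200 bp.

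**Figure D2:**
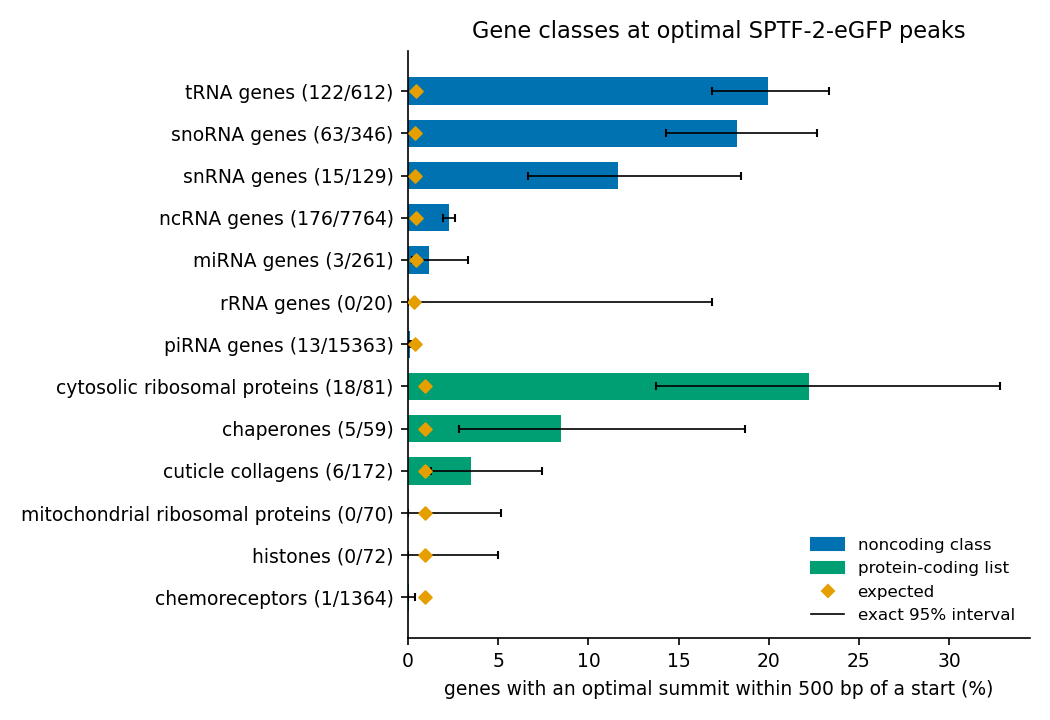
Share of genes with an optimal summit within 500 bp of an annotated start, in percent on the x axis, for the 7 noncoding classes (blue) and 6 of the protein-coding lists (green), with the counts in the labels; black lines are exact 95% intervals and orange diamonds the expected share, from shifted summits for noncoding classes and from all protein-coding genes for lists. tRNA genes (19.9%), snoRNA genes (18.2%) and cytosolic ribosomal protein genes (22.2%) stand far to the right of their expected shares.

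Of the protein-coding genes, those for cytosolic ribosomal proteins stood out. An optimal summit lay within 500 bp of a TSS of 187 of 19973 protein-coding genes (0.936%), and of 18 of the 81 cytosolic ribosomal protein genes (22.2%, 13.7 to 32.8), a 23.7-fold excess (Fisher's exact test, two-sided, adjusted p = 1.31e-18). The strongest of these peaks were at rpl-15 (signal 208), rpl-3 (203), rpl-35 (202) and rpl-26 (172). Of the 18 genes, 9 had a peak among the 407 strongest of both replicates, 3 in replicate 1 alone and 6 in replicate 2 alone. A snoRNA gene also started within 500 bp of the summit at 4 of the 18, and the excess was 25.6-fold when all summits at small RNA genes were left out, a choice made after the data were seen. None of the 70 mitochondrial ribosomal protein genes had a peak, which allows a share of up to 5.13%.

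Chaperone genes were also at peaks more often than other genes, with 5 of 59 (9.05-fold, Fisher's exact test, adjusted p = 0.00117). These were hsp-110 (signal 128), the endoplasmic reticulum Hsp70 gene hsp-3 (108), cct-7 (98.9), hsp-90 (96.0) and cct-8 (92.3), cct-7 and cct-8 being subunits of the CCT chaperonin. In the stronger part of the optimal set, 204 peaks, the chaperone excess was 8.06-fold and no longer passed Fisher's exact test (adjusted p = 0.102). Cuticle collagen genes had 6 of 172 at a peak (3.73-fold, Fisher's exact test, adjusted p = 0.0228), at col-85, col-98, col-122, col-106 and the neighbouring pair col-46 and col-47, which share a peak. When the labels of genes with a peak were rotated along the chromosomes in a permutation test, the collagen list missed the threshold (adjusted p = 0.0568). None of these 6 was among the 407 strongest peaks of both replicates. The collagen fold was 0.691 without replicate 1 and 1.18 without replicate 2, neither past the threshold, and it was 0 among the 204 strongest peaks. Chemoreceptor genes were at peaks less often than other genes, with 1 of 1364, sri-5, against 12.8 expected (0.0783-fold, Fisher's exact test, adjusted p = 9.54e-04). In windows of 1000 bp the count was 4 (0.191-fold), and in the 204 strongest peaks it was 0, both past the threshold. The other 25 of the 29 protein-coding lists did not pass the threshold, and 16 lists had no member at a peak. Expected counts in these 16 lists were 3.01 for F-box genes and at most 0.749 (homeobox genes) for the rest. Where so few are expected, a count of 0 says little about absence. Those without a peak included histones (72 genes), proteasome subunits (33), V-ATPase subunits (20), homeobox genes (80), germline and meiosis genes (33), cell cycle and replication genes (35), dosage compensation genes (10), major sperm proteins (31), vitellogenins (6), F-box genes (322), and the marker lists for intestine (15), hypodermis and seam (14), body wall muscle (18), pharynx (10) and neurons (22). Without replicate 1, 2 of 33 germline and meiosis genes (7.21-fold, Fisher's exact test, unadjusted p = 0.0313, adjusted p = 0.113) and 1 of 18 body wall muscle genes had a peak, and in windows of 1000 bp so did 2 proteasome genes and 1 histone gene. Splicing factors, with prp-40 and rsp-2 among 33 genes, reached an unadjusted p of 0.0381 in Fisher's exact test and an adjusted p of 0.137. They passed the threshold without replicate 2, with 4 of 33 (12.3-fold, Fisher's exact test, adjusted p = 0.00154), and in windows of 1000 bp (7.89-fold, Fisher's exact test, adjusted p = 0.00630), and had no peak among the 204 strongest. F-box genes, with none at a peak, passed as fewer than expected in windows of 1000 bp alone (Fisher's exact test, adjusted p = 0.0356). Oxidative phosphorylation had 2 of 47 genes at a peak, cox-5B and cox-5A. A single gene had a peak in each of the lists of translation factors (eef-1A.2, of 39), aminoacyl tRNA synthetases (ears-2, of 32), nuclear hormone receptors (nhr-1, of 269), detoxification genes (gst-27, 0.532% of the list), C-type lectins (clec-126, of 240) and actin and tubulin (tbb-1, of 18).

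Summits were closer to protein-coding starts than chance placement gave. Of the 407 summits, 164 (40.3%, 35.5 to 45.2) lay within 500 bp of a protein-coding TSS, against 22.7% for shifted summits, a 1.78-fold excess (permutation test, p = 0.0002, the smallest the shifts allow). Of the rest, 90 (22.1%) were in introns, 79 (19.4%) intergenic, 48 (11.8%) in other transcripts, 20 (4.91%) in coding exons and 6 (1.47%) in 3′ UTRs. The 25 strongest peaks near a protein-coding TSS had signals from 145 to 399. All of them, and the 5 strongest elsewhere, were among the 407 strongest peaks of both replicates.

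Many of these 25 peaks also had a small RNA gene nearby, a snoRNA in 7 and a tRNA in 7. Those without one included, after sptf-2, the peaks at tasp-1 (signal 343, 61 bp from the TSS), which encodes a taspase-like protease, mdt-26 (241), a Mediator subunit, rpl-15 with K11H12.8 (208), rpl-3, rpl-35, ears-2 with uncp-18 (191), wip-1 (167), atx-2 (155), the ataxin-2 gene, gei-4 (149) and dpf-3 (148). Peaks with a snoRNA gene were at twk-5 (263), a potassium channel gene, cfim-2 (196), a subunit of a pre-mRNA cleavage factor, chst-1 with C41C4.9 (186), rpl-26 with cpf-1 (172), tmem-107 with rps-26 (153), ppat-1 (153) and Y75B12B.11 (148). Those with a tRNA gene were at kvs-3 (170), twk-10 (166), ZK622.4 (161), C28G1.2 with sec-15 (151), ndx-2 (149), C24H11.2 (146) and Y54G2A.45 (145). Signal values near a TSS and elsewhere did not differ past the threshold (difference of median log2 signal, near minus other, -0.06, two-sided permutation test, p = 0.0884).

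The X chromosome held 99 of the 407 peaks (24.3%, 20.2 to 28.8), more than its 17.7% of the nuclear genome (1.38-fold, exact two-sided binomial test, p = 7.02e-04). Of the 103 peaks at tRNA genes 54 (52.4%) lay on X, as did 276 of the 612 annotated tRNA genes (45.1%). Among the 304 peaks away from tRNA genes, 45 (14.8%, 11 to 19.3) lay on X, 0.838-fold of its share of the length (exact binomial test, p = 0.202), in a comparison chosen after the data were seen. On the autosomes, 177 of 308 summits (57.5%, 51.7 to 63.1) lay in the central 50% of a chromosome by length (exact binomial test, p = 0.0102). Protein-coding starts had a share of 56.3% there, and against that share the difference did not pass the threshold (1.02-fold, exact binomial test, p = 0.730).

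Sequence at the summits was richer in GC boxes than sequence nearby. The core GC box, GGGCGG, occurred on either strand within 100 bp of 50 summits (12.3%) and in 16 flanking windows of equal width (3.93%), a ratio of 3.13 (exact two-sided McNemar test, adjusted p = 7.31e-05 over 12 motifs), and 5.00 without replicate 1. The longer form GGGCGGG was at 15 summits and in 1 flank (exact test, adjusted p = 0.00125), but without replicate 2 its ratio of 5.50 missed the threshold (adjusted p = 0.0539). It also missed it in windows of 50 bp either side (4 against 1, exact test, adjusted p = 0.643) and in the 204 strongest peaks (8 against 1, exact test, adjusted p = 0.0938). Against protein-coding starts without a peak its ratio was 3.20. The related CACC box, CACCC, was at 102 summits against 43 flanks (2.37-fold, exact test, adjusted p = 5.84e-07). The GA repeat GAGAGA was at 110 against 41 (2.68-fold, exact test, adjusted p = 1.00e-08), with a ratio of 1.64 without replicate 1. The 3′ splice site TTTCAG was at 73 summits against 130 flanks (0.562-fold, exact test, adjusted p = 2.51e-05). The GATA factor motif WGATAR was at 116 against 152 (0.763-fold, exact test, adjusted p = 0.0194), with 0.866 without replicate 1 and 0.855 without replicate 2, neither past the threshold. It also missed the threshold in windows of 50 bp either side (0.792), in the 204 strongest peaks (0.841), away from small RNA genes (0.808) and with overlapping peaks merged (0.833), and passed it against protein-coding starts without a peak (0.708). The Krüppel-like motif CCACGCCC, the E-box, the AP-1 site, the TATA box and both control hexamers did not pass. Against protein-coding starts without a peak the TATA box did, with a ratio of 0.564 (Fisher's exact test, adjusted p = 1.13e-07). Away from small RNA genes the E-box did, with 18 of 228 summits against 6 flanks (exact test, adjusted p = 0.0236), a setting chosen after the data were seen.

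The summit windows differed from the flanks in base composition as a whole, with 47.0% GC against 37.0%. Of 2080 hexamers, 361 were more frequent and 208 less frequent at summits past the threshold. The largest ratios among hexamers found in at least 1 flank were for GCGCGC (43 summits against 2 flanks), CCTAGG (15 against 1), CGGCCC (26 against 2), GCGGCC (57 against 5), CCCGGG (21 against 2), CCCCCG (50 against 5), GCGCAC (59 against 6), TGCGCA (29 against 3), CCCCGG (19 against 2) and ACCCCC (66 against 7). Compared with the other 35 hexamers made only of G and C, whose median ratio was 5.00, the GC box core ranked low, with 30 of them above it. It was also below 28 of 35 in the 228 peaks away from small RNA genes.

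**Figure D3:**
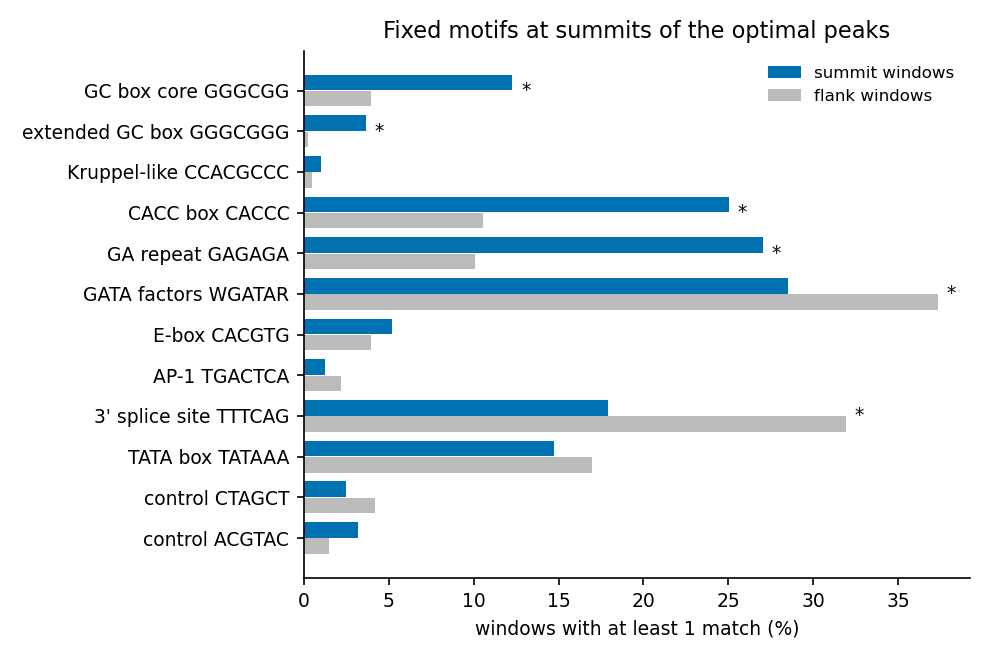
Percent of windows with at least 1 match to each of the 12 fixed motifs (x axis), in the windows 100 bp either side of the 407 summits (blue) and in flanking windows of the same width centred 500 bp away (grey); asterisks mark adjusted p below 0.05 in the exact McNemar test. The core GC box is at 12.3% of summits and 3.93% of flanks, and the 3′ splice site is less frequent at summits than in flanks.

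The replicates shared far more of their strongest peaks than chance gives, though most did not overlap. Of the 407 strongest peaks of replicate 1, 165 (40.5%, 35.7 to 45.5) overlapped one of the 407 strongest of replicate 2 by at least 1 bp, against a mean of 1.22 when the peaks of replicate 2 were shifted (136-fold, one-sided permutation test, p = 0.000999, the smallest that 1000 shifts can give). The fold was 276 when at least 50% of each peak had to overlap and 446 when summits had to lie within 100 bp, with 156 and 145 peaks shared. It was 8.10 in the 5000 strongest peaks, of which 29.7% overlapped, and 2.82 in the 20000 strongest, of which 40.2% overlapped. Of the 407 optimal peaks, 277 (68.1%, 63.3 to 72.6) were among the strongest 407 of replicate 1 and 252 (61.9%, 57.0 to 66.7) among those of replicate 2, with 163 in both and 41 in neither. The replicates did not differ in this share past the threshold (114 peaks in replicate 1 alone, 89 in replicate 2 alone, exact McNemar test, p = 0.0918). In the 5000 strongest peaks the shares were 99.0% and 95.8%, and there replicate 1 held more (exact McNemar test, p = 0.00720). Across the 405 optimal peaks found in both lists, signal values had a Spearman correlation of 0.235 and a Pearson correlation of log2 values of 0.481 (permutation p = 1e-05 for each, the smallest that 100000 pairings can give). These are correlations across peaks, which are not independent replicates. The optimal peaks are also the strongest of the pooled list, so they were selected on the combined signal of the replicates. Such a selection can lower the correlation, and shuffled pairings do not reproduce it. The values therefore do not measure the agreement of the replicates over all peaks.

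**Figure D4:**
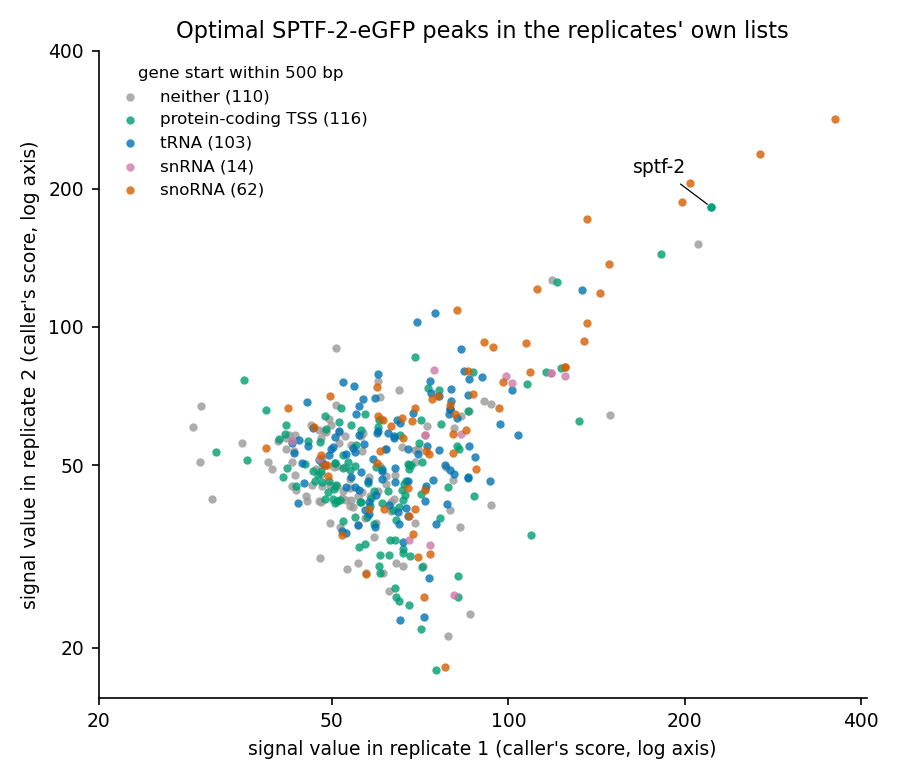
Signal value of the 405 optimal peaks found in both replicates' own lists, with replicate 1 on the x axis and replicate 2 on the y axis (the caller's scores, log axes), colored by the gene start within 500 bp of the summit. The peak at sptf-2 is marked, and 7 of the 10 strongest optimal peaks are at snoRNA genes. Across these 405 peaks, which were selected on pooled signal, the Spearman correlation is 0.235.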

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

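The tests of extra transgene copies and of GC content as the whole cause of the tRNA peaks were chosen only after the results they bear on were seen, as was the comparison of pooled peaks below the optimal set; the test of the X chromosome away from tRNA genes was chosen after the excess on X was seen and before its own result was.

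Signal at the same gene groups continued below the optimal set, in pooled peaks that the comparisons in the report do not use, which is why it is given here. Among the pooled peaks ranked 408 to 2000 (1593 peaks), 163 of the 490 tRNA genes without an optimal peak had a summit within 500 bp, against 8.29 for shifted summits (19.7-fold). The same held for 44 of 283 snoRNA genes (10-fold) and 11 of 114 snRNA genes (6.69-fold), each with an adjusted p of 2.80e-04 in a two-sided permutation test over 7 comparisons. Of the 63 remaining cytosolic ribosomal protein genes 24 had such a summit (12.6-fold, two-sided Fisher's exact test, adjusted p = 7.50e-20), as did 9 of 54 chaperone genes (5.52-fold, adjusted p = 1.08e-04) and 4 of 38 translation factor genes (3.49-fold, adjusted p = 0.0314). None of 31 aminoacyl tRNA synthetase genes did. These are values from the pooled list without a check between replicates.

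The peaks at tRNA genes were weighed against GC content and shared reads. tRNA genes with a peak had a median GC content 1.73 percentage points above those without, in a window of the usual peak width around the start (42.2% against 40.4%, two-sided permutation test, p = 0.00954), so GC content may contribute to which tRNA genes have a peak. The test treats tRNA genes as independent, although neighbours can share a summit and copies can have nearly the same sequence. As the whole cause, the mean GC content of this window is argued against: genome windows away from tRNA genes, matched in that mean, had a summit within 500 bp in 0.452% of cases, against 19.9% (16.8 to 23.3) of tRNA genes. The match does not cover a shorter GC-rich stretch within the window. For shared reads, the median share of 36-base sequences found more than once in the genome was 14.4% around tRNA genes with a peak and 14.7% around those without (difference -0.293, permutation test, p = 0.548), which leaves reads shared between copies open for these genes. Of the 19 tRNA genes with no such repeat, 2 (10.5%, 1.30 to 33.1) had a peak, above the 0.455% of shifted summits. Of the other 593 tRNA genes, 120 (20.2%) had one (two-sided Fisher's exact test between the groups, p = 0.393). Repeats were sought only within the usual peak width around the start. A summit up to 500 bp away was counted, and it can belong to a neighbouring tRNA gene, so the 19 genes do not decide on shared reads. No biological explanation was tested, and whether these genes gather reads without the tagged protein was not analysed here.

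The excess of peaks on the X chromosome was weighed against the positions of tRNA genes. Among peaks away from tRNA genes, 14.8% lay on X, with an interval of 11 to 19.3 that holds the 17.7% of the length, so the concentration of tRNA genes on X may account for the excess. The test could have come out the other way, had that interval stayed above the share of the length. It rests on the same peaks that showed the excess, and no biological explanation was tested.

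The peaks at sptf-2 were weighed against extra copies of its locus, which a transgene can add. The median signal of the 20 pooled peaks within 20 kb of the sptf-2 start, leaving out the nearest 1 kb, was 47.0, at percentile 96.7 of the same median around 19580 other protein-coding starts (median 37.4). The 20 peaks included some inside sptf-2 (signals 92.1 and 53.9) and at the tRNA gene inside cutl-12 (163 and 84.2). With these left out, the middle signals of the remaining peaks were 39.95 and 40.79, nearer to the 37.4 elsewhere than 47.0 is. The raised median therefore rests in part on peaks inside sptf-2 and at this tRNA gene. Such peaks were not left out around the other starts, and no percentile was taken without them. The percentile of 96.7 therefore does not speak for the flanking sequence alone. Added copies of a region could raise such a median, since each copy yields reads. A control with the same copies could offset this, and the strain behind the control alignment is not stated here. Whether part of the signal at sptf-2 comes from copy number and not from binding is not settled by this median. Around unc-119, of which the transgene also carries a working copy, there were 2 pooled peaks in the same window, against a median of 11 elsewhere; how much of the native unc-119 region the transgene holds is not given in the sources used here. Binding by SPTF-2 at its own gene stays open, and no biological explanation was tested.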

How the results depend on the processing

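Alternatives that left out or merged peaks near small RNA genes, tRNA genes or each other were chosen after the data were seen; the rest were fixed before. Of 39 alternative values of the main results other than numbers of calls, 33 kept their direction and their side of the threshold or, for shares without a test, stayed within their interval. The exceptions follow. Away from tRNA genes the X chromosome fold was 0.838. For the central part of the autosomes the fold was 1.02 against protein-coding starts and 1.07 away from small RNA genes, neither past the threshold. With the 5000 strongest peaks per replicate the optimal peaks found were 99.0% and 95.8%, by construction of the longer list, and the difference of 3.19 percentage points passed the threshold. The excess near protein-coding starts ranged from 1.41-fold (1000 bp windows) to 2.25-fold (away from small RNA genes), and without a replicate from 1.62 to 1.91. The number of gene lists and classes past the threshold, 9 in the main setting, ranged from 6 to 11, and that of motifs, 6 in the main setting, from 4 to 7, with calls both lost and gained. The overlap of the replicates passed its test in every alternative, with folds from 2.82 (20000 strongest peaks) to 446 (summits within 100 bp). Cuticle collagens had a fold of 0 among the 204 strongest peaks and 0.691 to 1.18 without a replicate. Splicing factors had a fold of 0 in the same 204 peaks. The TATA box ratio was 1.03 in windows of 50 bp either side (0.870 in the main setting) and the E-box ratio 0.4 in the 204 strongest peaks (1.31 in the main setting), none of these past the threshold. The cause was not tested, except where stated. For single lists and motifs past the threshold in any setting, 112 of 136 alternative values held, 13 fell short of the threshold, 6 newly passed it and 5 changed direction. Those newly past it were splicing factors (1000 bp windows and without replicate 2), F-box genes (1000 bp windows), miRNA genes (without replicate 2), the TATA box (against starts without a peak) and the E-box (away from small RNA genes). Folds of tRNA, snoRNA and snRNA genes away from small RNA genes are 0 by construction and are left out of these counts, and GGGCGGG had no match in any flank there (8 summits against 0), so it has no ratio. No paired analysis was possible because there is 1 group. Depth is unknown, and with 2 replicates a leave-one-out value rests on 1 library.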

Other observations

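All comparisons in this part were chosen after the data were seen.

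Called peaks were not spread evenly over tRNA kinds. At least 1 repeated 36-base sequence lay around the start of 593 tRNA genes, so copies may share reads and gain or lose peaks together. The tests below treat genes as independent and do not account for this. Of 34 alanine tRNA genes 19 had an optimal peak (55.9%, two-sided Fisher's exact test against all other tRNA genes, adjusted p = 3.98e-05 over 22 categories), as did 9 of 13 cysteine tRNA genes (69.2%, adjusted p = 0.00147). Neighbouring tRNA genes can share a summit, and 1 peak on X had 5 tRNA gene starts within 500 bp. With genes of a kind whose starts lay within 1000 bp of their neighbour counted once, alanine had 17 of 30 (Fisher's exact test, adjusted p = 3.47e-04), and cysteine, with 6 of 10, missed the threshold (Fisher's exact test, adjusted p = 0.0968). By gene, threonine followed with 13 of 34 (Fisher's exact test, adjusted p = 0.0939) and lysine with 15 of 46 (adjusted p = 0.181), and the lowest shares among kinds with at least 20 genes were histidine, with 1 of 20, and valine, with 2 of 31. 

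Among splice leader genes, 6 of 18 sls-2 genes, which make the SL2 RNA spliced onto downstream genes of operons, had an optimal peak, and 0 of 12 sls-1 genes, which make the SL1 RNA. The difference between these groups was not tested. Whether reads can be placed at single copies of these genes was not checked, so the lack of a peak at sls-1 may not mean a lack of binding. Among the sls-2 genes, sls-2.2 and sls-2.3 shared a peak (signal 92.7), and the sls-2.9 peak (95.5) had its summit nearer to a tRNA gene start. Of the other 99 snRNA genes 9 had a peak, among them sup-6 and sup-39. The sup-39 peak was shared with mir-1831, which is annotated as an snRNA gene and also counted in the 9. The miRNA genes with a peak were mir-51 (signal 240), mir-52 (95.2) and mir-87 (114).

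Peaks at small RNA genes were shared between the replicates more often than other optimal peaks. Of the 179 peaks at tRNA, snoRNA or snRNA genes, 105 (58.7%, 51.1 to 66) were among the strongest 407 of both replicates, against 58 of the other 228 (25.4%, 19.9 to 31.6, two-sided Fisher's exact test, p = 1.17e-11). Since they also have higher signal, the shares were compared within the 204 strongest optimal peaks, where they were 81.7% of 120 and 61.9% of 84 (Fisher's exact test, p = 0.00213). Among the weaker peaks they were 11.9% of 59 and 4.17% of 144 (Fisher's exact test, p = 0.0572). This split does not match signal within each part, as 35 of the 50 strongest optimal peaks were at small RNA genes. The shares therefore do not separate the kind of gene from the signal.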
